A study of Mus musculus with 10 samples.

How the data were processed

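The samples were brain cortex of 6-month-old mice, with 5 libraries labelled ctrl (genotype wild type for Mic19) and 5 labelled BKO (genotype Mic19 knockout). Per the labels, total RNA was extracted with Trizol and libraries were made with an MGIEasy kit. The deposited table holds FPKM values that the authors computed, for 22198 genes in 10 columns, 1 per library, rounded to 2 decimals. The authors' notes name STAR, HTSeq and the mm39 build without versions, and state no filter and no formula for the FPKM. The table had 0 columns of other samples. No counts were used here, so the precision from read depth is unknown, and no counting intervals are given. Relative depth was estimated from the steps between the lowest values of each library, on the ground that 1 fragment in a gene gives a step inversely proportional to depth. It is approximate, since 28 of 45 pairs of libraries lay within 0.03 log2 of the fitted depths. No coordinates are given, because the reference at hand was another build than mm39. Groups were taken from the labels.

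Genes with at least 0.5 FPKM in at least 5 of the 10 libraries were tested, 14447 in all. The values log2(FPKM + 0.5) were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend in the variances, 2-sided), and a gene changed when its Benjamini-Hochberg adjusted p was under 0.05. SE is limma's moderated standard error and SD the standard deviation between libraries. For 41 gene lists the members that passed were counted over all genes tested and adjusted over the list alone. The 40 lists with at least 3 tested members were also set against all other genes with limma's camera, at a preset correlation of 0.01 between genes and at a correlation estimated from the data, adjusted over the lists. List means per library were compared with an exact permutation test, 2-sided, whose smallest p was 0.00794. The same exact test was used for Chchd3 and for relative depth. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 made the summaries and figures.

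The test, the 41 lists, the naming rule and the alternatives were set before the data were examined. Always named were Chchd3, Cgas, Sting1, Phgdh, Psat1, Psph, Shmt2, Gfap, Aif1, Tnf, Il1b, Il6 and Cxcl10. To these came the 10 largest rises and 10 largest falls with an adjusted p under 0.05, no overlap between the groups, a mean of at least 1 FPKM in the higher group and an ordinary gene name. From each list described, up to 4 members with the smallest p could be named. That no member was named from the lists of B cells, T and NK cells, choroid plexus, red blood cells, neutrophils and monocytes, meninges, mural cells, striatum, hippocampus, thalamus, glycolysis, nuclear respiratory complexes and mitochondrial DNA maintenance was decided after the results were seen. The trend in camera's variances was also set after a first run without it, which called 10 lists with an estimated correlation where 8 were called with it. A further 4 lists were chosen after the data were seen and are given only in the closing section. Gene names were matched through their older symbols where the table used these. Mx1, Mx2, Fcrls and Ighm were not analysed here. Some results for single genes that the rule would name were left out of the text because they are withheld for evaluation.

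The alternatives were pseudocounts of 0.1 and 1, no filter, a filter at 2 FPKM, median-of-ratios rescaling, rescaling to an equal sum per library, quantile normalization, the replicate number as a block, library quality weights, a robust fit, each library left out in turn, an estimated correlation and lists without shared genes. Tests that need counts were not run. Of the 126 ways to split the libraries into 5 and 5, 100 were fitted. The fit was tested on simulated data of the same size with changes of known size. It recovered 24.5% of 49 genes changed by 0.25 on the log2 scale, 68% of 50 changed by 0.5, 87.5% of 48 changed by 1 and 98% of 50 changed by 2, and it called 8 of 14148 unchanged genes. Of 40 simulated lists without a change 0 were called by camera, and a list shifted by 0.5 was called. The simulated genes varied independently of one another, so this does not test camera's calls on lists whose genes vary together.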

Results

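RNA sequencing had been performed on brain cortex of 6-month-old mice. There were 5 libraries labelled ctrl, with wild-type Mic19, and 5 libraries labelled BKO, with Mic19 knocked out. Mic19, whose gene symbol is Chchd3, is a subunit of the MICOS complex, which shapes the cristae of the inner mitochondrial membrane. The comparison of the genotypes was aimed at inflammation genes, and the study's title also names leakage of mitochondrial DNA, cGAS-STING signalling, serine metabolism and epilepsy. Each library had an FPKM value (fragments per kilobase of transcript, scaled to the library's total) for 22198 genes, of which 13438 to 13720 stood at 1 FPKM or more. The FPKM values of a library summed to between 730340 and 766786. Read totals were not used here. The steps between low values put the relative depth of the libraries at 0.863 to 1.21, as an approximate estimate. It was 1.04 ± 0.140 (SD, n = 5) in ctrl and 0.976 ± 0.108 (SD, n = 5) in BKO (exact permutation test, 2-sided, p = 0.460). The labels do not say that each library came from its own mouse, so the p-values measure only the spread between these libraries.

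Chchd3, the gene named as knocked out, was not lower in the libraries labelled BKO. Its level was 78.4 ± 3.53 FPKM (SD, n = 5) in the libraries labelled ctrl and 88.2 ± 4.54 FPKM (SD, n = 5) in those labelled BKO. The ctrl libraries 1 to 5 stood at 73.1, 77.3, 80.6, 79.0 and 82.3 FPKM, and the BKO libraries 1 to 5 at 94.2, 89.4, 88.3, 81.5 and 87.7 FPKM. Of the 5 BKO libraries, 4 lay above every ctrl library (exact permutation test, 2-sided, p = 0.0159). Fold changes are given on the log2(FPKM + 0.5) scale, which understates the changes of genes with low values. On it the difference was 0.17 (SE 0.047), and it did not pass the test over all genes (limma adjusted p = 0.0528). It passed after rescaling to an equal sum per library (0.19, limma adjusted p = 0.0227), after quantile normalization (0.19, limma adjusted p = 0.0240), without ctrl 5 (0.19, limma adjusted p = 0.0403) and without BKO 4 (0.20, limma adjusted p = 0.0288). The values cover whole genes and exon-level values were not analysed here, so they do not test the loss of part of the gene. The whole-gene level thus neither supports the genotype labels nor rules them out, and each direction given here is that of the libraries as labelled. Among 11 other MICOS subunits and partner proteins, such as Dnajc11 and Mtx1, none changed, and none had an unadjusted limma p under 0.05. Their log2 fold changes ran from -0.04 to 0.09 (camera adjusted p = 0.706).

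In the cortex labelled BKO, genes of the integrated stress response and of serine synthesis rose. Of the tested genes, 18 of 32 of the interferon response, 11 of 22 of reactive astrocytes and 5 of 15 of MHC class I antigen presentation rose as well, while all 12 markers of myelinating oligodendrocytes fell. Nupr1, a stress-induced chromatin-associated protein, went from 31.1 ± 3.58 FPKM (SD, n = 5) in ctrl to 193 ± 15.1 FPKM (SD, n = 5) in BKO. Gfap, the intermediate filament of astrocytes, went from 85.4 ± 5.55 FPKM (SD, n = 5) to 435 ± 71.1 FPKM (SD, n = 5). Mbp, a main protein of myelin, went from 1223 ± 87.9 FPKM (SD, n = 5) to 457 ± 67.8 FPKM (SD, n = 5). Of 14447 genes tested, 836 changed (limma, adjusted p under 0.05), 480 being higher and 356 lower in BKO. By more than 1 on the log2 scale, 53 were higher and 51 lower. All 5 BKO libraries lay above all 5 ctrl libraries for 523 genes and below them for 447 genes, where chance gives 0.794% of genes in both directions together. Among the genes named here as changed, the groups overlapped for Cxcl10, Cxcl16, C1qb, Nefh, Nefm, Snap25 and Hspe1 and for no other. The first principal component held 28.9% of the variance and separated the labels. Of 40 gene lists that could be tested, 19 moved against all other genes with a preset correlation between genes (camera, limma), and 8 with a correlation estimated from the data. In the exact test of list means, every BKO library lay above every ctrl library for the stress response, both serine, interferon, cGAS-STING and NF-kB lists. So it did for complement, MHC class I and II, activated microglia, reactive astrocytes, astrocyte identity and mitochondrial chaperones and proteases. For oligodendrocytes every BKO library lay below every ctrl library. Each had p = 0.00794 (exact permutation test, 2-sided), and 0.0232 adjusted over the lists.

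The 10 genes that rose most were Ostn, Gdf15, Slc1a5, Hmox1, Trib3, Nupr1, Gfap, Cyb5r2, Adm2 and Atf5. Ostn, which encodes the secreted peptide osteocrin, rose by 3.91 (SE 0.266, limma adjusted p = 2.7e-07), from 0.338 ± 0.408 to 11.1 ± 1.99 FPKM (SD, n = 5 each). Gdf15, a secreted stress cytokine, rose by 3.59 (SE 0.175, limma adjusted p = 8.66e-09), from 0.238 ± 0.155 to 8.30 ± 1.47 FPKM. Hmox1, haem oxygenase, rose by 2.76 (SE 0.123, limma adjusted p = 3.65e-09), and Atf5, a stress-response transcription factor, by 2.04 (SE 0.0854, limma adjusted p = 1.84e-09). The 10 genes that fell most were Klk6, Anln, Fa2h, Hapln2, Fbxw15, Ppp1r14a, Galnt6, Abca8a, Opalin and Mobp. Klk6, a secreted serine protease, fell by 1.95 (SE 0.129, limma adjusted p = 2.11e-07). Fa2h, which hydroxylates the fatty acids of myelin sphingolipids, fell by 1.89 (SE 0.118, limma adjusted p = 1.14e-07). Hapln2, a link protein at nodes of Ranvier, fell by 1.88 (SE 0.0901, limma adjusted p = 7.53e-09).

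**Figure D1:**
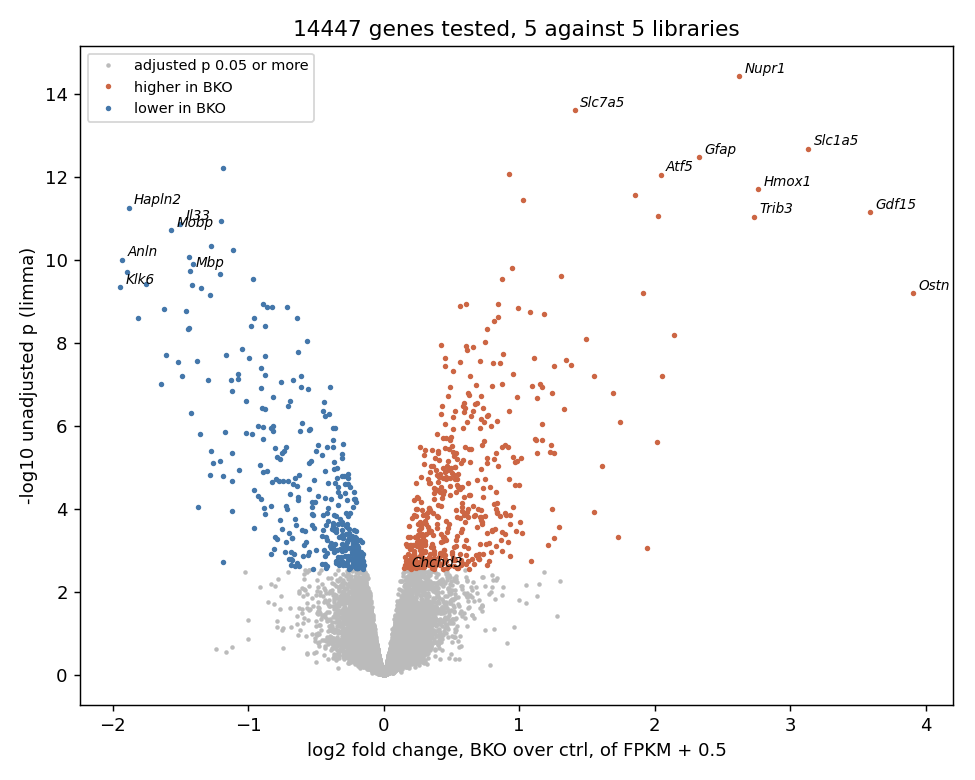
Each point is 1 of the 14447 genes tested, with the log2 fold change of BKO over ctrl on the horizontal axis and the unadjusted limma p as -log10 on the vertical axis. The 480 genes higher and 356 lower in BKO are coloured, Chchd3 lies below the threshold at 0.17, and Nupr1 has the smallest p.

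Of the 25 tested genes of the ATF4 and integrated stress response list, 22 rose and none fell, and 24 rose when adjusted over the list alone. The list rose against all other genes (camera adjusted p = 3.25e-51, and adjusted p = 0.000103 with an estimated correlation), and its median log2 fold change was 0.88. The amino acid transporter subunits Slc7a5 and Slc3a2 rose by 1.41 (SE 0.0455, limma adjusted p = 1.84e-10) and 0.92 (SE 0.0385, limma adjusted p = 1.84e-09). Trib3, a pseudokinase induced by ATF4 and CHOP, rose by 2.73 (SE 0.135), from 0.982 ± 0.268 to 9.25 ± 1.14 FPKM (SD, n = 5 each). The list mean of every BKO library lay above that of every ctrl library (exact permutation test, 2-sided, p = 0.00794, the smallest these groups allow, and 0.0232 adjusted over the lists).

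All 3 enzymes of serine synthesis from glycolytic intermediates rose, and 3 when adjusted over the list alone (camera adjusted p = 1.07e-07, and adjusted p = 0.0277 with an estimated correlation). Of the 3, Phgdh and Psat1 also belong to the stress response list, so the lists are not separate. Phgdh, the first enzyme of the pathway, rose by 0.64 (SE 0.062, limma adjusted p = 9.82e-06), from 63.5 ± 6.47 to 98.7 ± 2.68 FPKM (SD, n = 5 each). Psat1 rose by 0.44 (SE 0.0565, limma adjusted p = 0.000161) and Psph by 0.63 (SE 0.0655, limma adjusted p = 2.05e-05). Shmt2, the mitochondrial serine hydroxymethyltransferase, rose by 0.42 (SE 0.0649, limma adjusted p = 0.000794). In the wider list of serine and one-carbon metabolism, which shares 6 genes with the stress response list, 10 of 27 rose and 1 fell, against 11 and 2 when adjusted over the list alone (camera adjusted p = 4.21e-08, and adjusted p = 0.0357 with an estimated correlation). Slc1a5, a neutral amino acid transporter, rose by 3.13 (SE 0.118, limma adjusted p = 1.04e-09), from 1.30 ± 0.277 to 15.2 ± 1.63 FPKM (SD, n = 5 each). Aldh1l1, a folate enzyme of astrocytes, rose by 0.51 (SE 0.0486, limma adjusted p = 8.12e-06). The 1 that fell was Gldc, of the glycine cleavage system, by 0.29 (SE 0.0691, limma adjusted p = 0.0197), named after its values were seen. Its call was lost without ctrl 1, BKO 3 or BKO 4 (limma adjusted p = 0.0518 to 0.0544), no member fell in the replicate block, and 2 fell without ctrl 2, BKO 2 or BKO 5. The call on the wider list was lost when genes shared with other lists were left out (camera adjusted p = 0.0593).

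**Figure D2:**
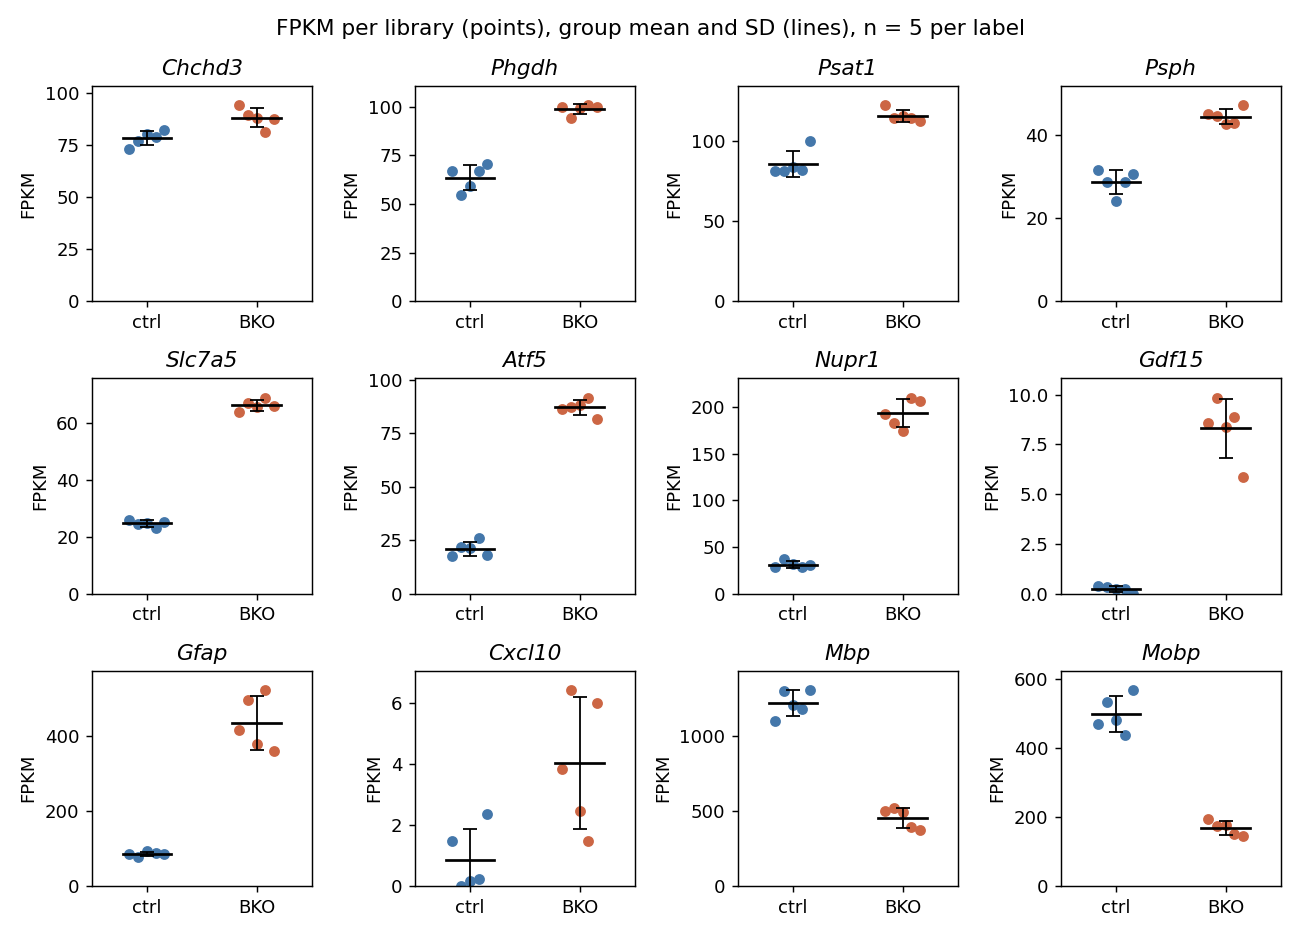
FPKM of 12 genes in each library (points), with the mean and SD of the 5 libraries per label (lines), on axes that start at 0. Chchd3 and Cxcl10 overlap between the labels, and the BKO libraries lie above every ctrl library for Phgdh, Psat1, Psph, Slc7a5, Atf5, Nupr1, Gdf15 and Gfap and below every one for Mbp and Mobp.

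Of 32 tested genes of the type I interferon response, 18 rose and none fell, and 23 rose when adjusted over the list alone (camera adjusted p = 1.27e-16, and adjusted p = 0.0277 with an estimated correlation). The number that rose was 13 to 17 with 1 library left out, 15 in the replicate block and 16 after quantile normalization. Lgals3bp, a secreted glycoprotein, rose by 0.98 (SE 0.105, limma adjusted p = 2.47e-05). Ifitm3, an antiviral membrane protein, rose by 1.11 (SE 0.145, limma adjusted p = 0.000167), from 12.7 ± 3.15 to 27.5 ± 2.26 FPKM (SD, n = 5 each). Irf9, part of the interferon-activated transcription complex, rose by 0.44 (SE 0.0757, limma adjusted p = 0.00191). The chemokine Cxcl10 rose by 1.94 (SE 0.464, limma adjusted p = 0.0214), from 0.844 ± 1.03 to 4.04 ± 2.17 FPKM (SD, n = 5 each). Its call was lost without ctrl 2, ctrl 3, ctrl 4, BKO 2 or BKO 5 (limma adjusted p = 0.0553 to 0.0628) and without the filter on low values (limma adjusted p = 0.0573). Of 8 tested genes of the cGAS-STING pathway, 2 rose, and 2 when adjusted over the list alone. They were Ifi204, an interferon-inducible DNA-binding protein, by 0.82 (SE 0.172, limma adjusted p = 0.00921; 1.45 and 0.54 with pseudocounts of 0.1 and 1), and Irf7, also in the interferon list, by 0.80 (SE 0.171). The pathway list was called with the preset correlation (camera adjusted p = 0.00933) and not with an estimated one (adjusted p = 0.0703 with an estimated correlation). Nor was it called with a stricter filter (camera adjusted p = 0.110) or without genes of other lists (camera adjusted p = 0.0562). In the first run, without a trend in camera's variances, it was called with both correlations (adjusted p = 0.0487 with an estimated correlation). The mean of the pathway list was higher in every BKO library than in every ctrl library (exact permutation test, 2-sided, p = 0.00794, and 0.0232 adjusted over the lists). Sting1 stood at 3.53 ± 1.28 FPKM in ctrl and 3.97 ± 0.791 FPKM in BKO (SD, n = 5 each), a log2 difference of 0.19 (SE 0.198, limma adjusted p = 0.697). It was 0.02 without ctrl 2 and 0.34 without ctrl 1, the lowest and highest with 1 library left out, and 0.12 with library weights. Cgas lay below the filter, at 0.364 ± 0.171 and 0.436 ± 0.179 FPKM (SD, n = 5 each), and Ifnb1 was listed at 0 in all 10 libraries.

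Of 18 tested cytokine, chemokine and inflammasome genes, 2 rose and 1 fell, against 5 and 1 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.315). Il33, an alarmin that oligodendrocytes also express, fell from 37.6 ± 4.27 to 12.9 ± 0.836 FPKM (SD, n = 5 each; limma adjusted p = 1.24e-08). Those that rose were Cxcl10 and Cxcl16, the latter by 0.68 (SE 0.170, limma adjusted p = 0.0282). The call on Cxcl16 was lost without ctrl 3, ctrl 4, BKO 1, BKO 3 or BKO 5 (limma adjusted p = 0.0555 to 0.0784), without the filter on low values (limma adjusted p = 0.0549) and in the replicate block (limma adjusted p = 0.0549). The number that rose was 0 without ctrl 3 or BKO 5 and 1 without ctrl 2, ctrl 4, BKO 1 or BKO 3. Il1b stood at 0.818 ± 0.534 FPKM in ctrl and 0.468 ± 0.220 FPKM in BKO (SD, n = 5 each), a log2 difference of -0.40 (SE 0.257, limma adjusted p = 0.477). It was -0.19 without ctrl 4, -0.25 without BKO 1 and -0.64 with a pseudocount of 0.1. Tnf and Il6 lay below the filter, Tnf being above 0 in 1 ctrl and 2 BKO libraries and Il6 in 1 of each. Of 14 NF-kB targets, 1 rose, and 2 when adjusted over the list alone. It was Bcl3, by 0.83 (SE 0.195, limma adjusted p = 0.0192; 1.25 with a pseudocount of 0.1), whose call was lost without BKO 3 (limma adjusted p = 0.0533), and 2 rose without ctrl 5. Icam1, an adhesion molecule, passed under 5 of the planned settings with all libraries (limma adjusted p = 0.0435 to 0.0492). The list was called with the preset correlation (camera adjusted p = 0.00775), but not with an estimated one (adjusted p = 0.0610 with an estimated correlation) or with a stricter filter (camera adjusted p = 0.482). In the first run, without a trend in camera's variances, the list was called with both correlations (adjusted p = 0.0393 with an estimated correlation). The mean of the NF-kB list was higher in every BKO library than in every ctrl library (exact permutation test, 2-sided, p = 0.00794, and 0.0232 adjusted over the lists).

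Of 15 tested genes of MHC class I antigen presentation, 5 rose and none fell, and 10 rose when adjusted over the list alone (camera adjusted p = 2.77e-09, and adjusted p = 0.0277 with an estimated correlation). They were H2-D1, H2-K1, B2m, H2-Q4 and Tap2, the last named after its values were seen. H2-D1, a heavy chain, rose by 0.74 (SE 0.0625, limma adjusted p = 2.31e-06), and B2m, the shared light chain, by 0.34 (SE 0.055, limma adjusted p = 0.00115). Of 7 class II genes, 1 rose, and 3 when adjusted over the list alone. It was Cd74, the invariant chain, by 0.90 (SE 0.172, limma adjusted p = 0.00463), and 2 rose without BKO 1. That list was called with the preset correlation (camera adjusted p = 0.0162) and not with an estimated one (adjusted p = 0.206 with an estimated correlation). Of 13 complement genes, 5 rose and none fell, and 7 rose when adjusted over the list alone (camera adjusted p = 1.25e-06, and adjusted p = 0.0373 with an estimated correlation). C4b rose by 1.31 (SE 0.0828, limma adjusted p = 1.34e-07) and C1qa by 0.39 (SE 0.0656, limma adjusted p = 0.00156). The others were Itgb2, C1qb and C3ar1, the last named after its values were seen. The call on Itgb2 was lost without ctrl 1, ctrl 2, ctrl 4, BKO 1, BKO 2 or BKO 4 (limma adjusted p = 0.0578 to 0.0685) and in the replicate block (limma adjusted p = 0.0913). That on C1qb was lost without ctrl 2, ctrl 3, ctrl 5, BKO 1, BKO 2 or BKO 4 (limma adjusted p = 0.0502 to 0.0719) and without the filter (limma adjusted p = 0.0511). That on C3ar1 was lost without ctrl 2, ctrl 4, BKO 2, BKO 3, BKO 4 or BKO 5 (limma adjusted p = 0.0540 to 0.0682). The number of complement genes that rose was thus 2 without ctrl 2, BKO 2 or BKO 4 and 3 without ctrl 4 or BKO 1. C4b, the H2 genes and the interferon-induced families have near-identical relatives, among which reads can be divided, so their single values are uncertain.

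Of 22 tested reactive astrocyte genes, 11 rose and none fell, and 13 rose when adjusted over the list alone (camera adjusted p = 5.6e-11, and adjusted p = 0.030 with an estimated correlation). Gfap rose by 2.33 (SE 0.0907, limma adjusted p = 1.23e-09) and Vim, another intermediate filament, by 0.80 (SE 0.0737, limma adjusted p = 5.54e-06). The transcription factor Stat3 rose by 0.53 (SE 0.0601) and Ggta1 by 0.83 (SE 0.0995). Of 15 astrocyte identity genes, 5 rose, namely Aldh1l1, Atp1b2, Kcnj10, Aqp4 and Slc1a3, the last named after its values were seen. Adjusted over the list alone, 5 rose and 4 fell, so its members went both ways, and 1 fell over all genes without ctrl 2, ctrl 3, BKO 2 or BKO 5. That list was not called (camera adjusted p = 0.0710), except after quantile normalization (camera adjusted p = 0.0103) and without ctrl 1, BKO 3 or BKO 5 (camera adjusted p = 0.0382 to 0.0439). Its mean was higher in every BKO library than in every ctrl library, by 0.11 on the log2 scale (exact permutation test, 2-sided, p = 0.00794, and 0.0232 adjusted over the lists). Of 22 activated microglia genes, 9 rose and 1 fell, against 13 and 1 when adjusted over the list alone. The number that rose was 6 to 9 with 1 library left out, and 7 in the replicate block and after quantile normalization. Gpnmb, a lysosomal glycoprotein, rose by 1.91 (SE 0.130, limma adjusted p = 2.65e-07) and the lectin receptor Clec7a by 2.02 (SE 0.266, limma adjusted p = 0.000192; 3.31 with a pseudocount of 0.1). Cd63 rose by 0.69 (SE 0.0754) and lysozyme Lyz2 by 0.76 (SE 0.0887). The 1 that fell was Fth1, ferritin heavy chain, by 0.28 (SE 0.0538, limma adjusted p = 0.00461), named after its values were seen, and no member fell after quantile normalization. The list was called with the preset correlation (camera adjusted p = 4.62e-08) and not with an estimated one (adjusted p = 0.0758 with an estimated correlation). Of 14 genes of microglia identity none changed (limma; 2 higher and 1 lower at unadjusted p under 0.05). Their list was not called (camera adjusted p = 0.182), except without ctrl 4 (camera adjusted p = 0.0172) or BKO 5 (camera adjusted p = 0.0439). Among them Aif1 stood at 13.5 ± 0.480 FPKM in ctrl and 17.6 ± 3.64 FPKM in BKO (SD, n = 5 each; log2 difference 0.35, SE 0.114, limma adjusted p = 0.104). It passed without BKO 2 (limma adjusted p = 0.0490) or BKO 5 (limma adjusted p = 0.0199), and 1 member of the list rose without ctrl 4, BKO 2 or BKO 5.

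All 12 oligodendrocyte genes fell, under each of the 4 scalings tried and with any 1 library left out. So did 12 when adjusted over the list alone (camera adjusted p = 5.99e-37, and adjusted p = 0.0199 with an estimated correlation). Their median log2 fold change was -1.42, with a range from -1.61 to -0.96. Mobp, a myelin protein, fell by 1.57 (SE 0.0823, limma adjusted p = 1.66e-08), from 499 ± 52.3 to 168 ± 19.6 FPKM (SD, n = 5 each). Aspa, which cleaves N-acetylaspartate, fell by 1.43 (SE 0.0838), Ugt8a, which makes the galactolipids of myelin, by 1.41 (SE 0.0848) and Mbp by 1.43 (SE 0.0886, limma adjusted p = 1.11e-07). Of 9 genes of oligodendrocyte precursors, 2 fell, and 2 when adjusted over the list alone. They were transcription factors of the whole lineage, Olig1 by 0.44 (SE 0.0482, limma adjusted p = 3.14e-05) and Sox10 by 0.89 (SE 0.109, limma adjusted p = 9.65e-05), and 3 members fell without BKO 2. Their list was called with the preset correlation (camera adjusted p = 0.00401) and not with an estimated one (adjusted p = 0.373 with an estimated correlation). Of 19 genes of cholesterol synthesis, 7 fell and none rose, and 12 fell when adjusted over the list alone. The list was called with the preset correlation (camera adjusted p = 2.3e-09) and not with an estimated one (adjusted p = 0.105 with an estimated correlation). Its mean was lower in BKO, with overlap between the groups (exact permutation test, 2-sided, p = 0.0159, and 0.0434 adjusted over the lists). Idi1, an isomerase of the pathway, fell by 0.43 (SE 0.0762, limma adjusted p = 0.00221). The number that fell was 3 without ctrl 2 and 4 without ctrl 3, BKO 1 or BKO 2.

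**Figure D3:**
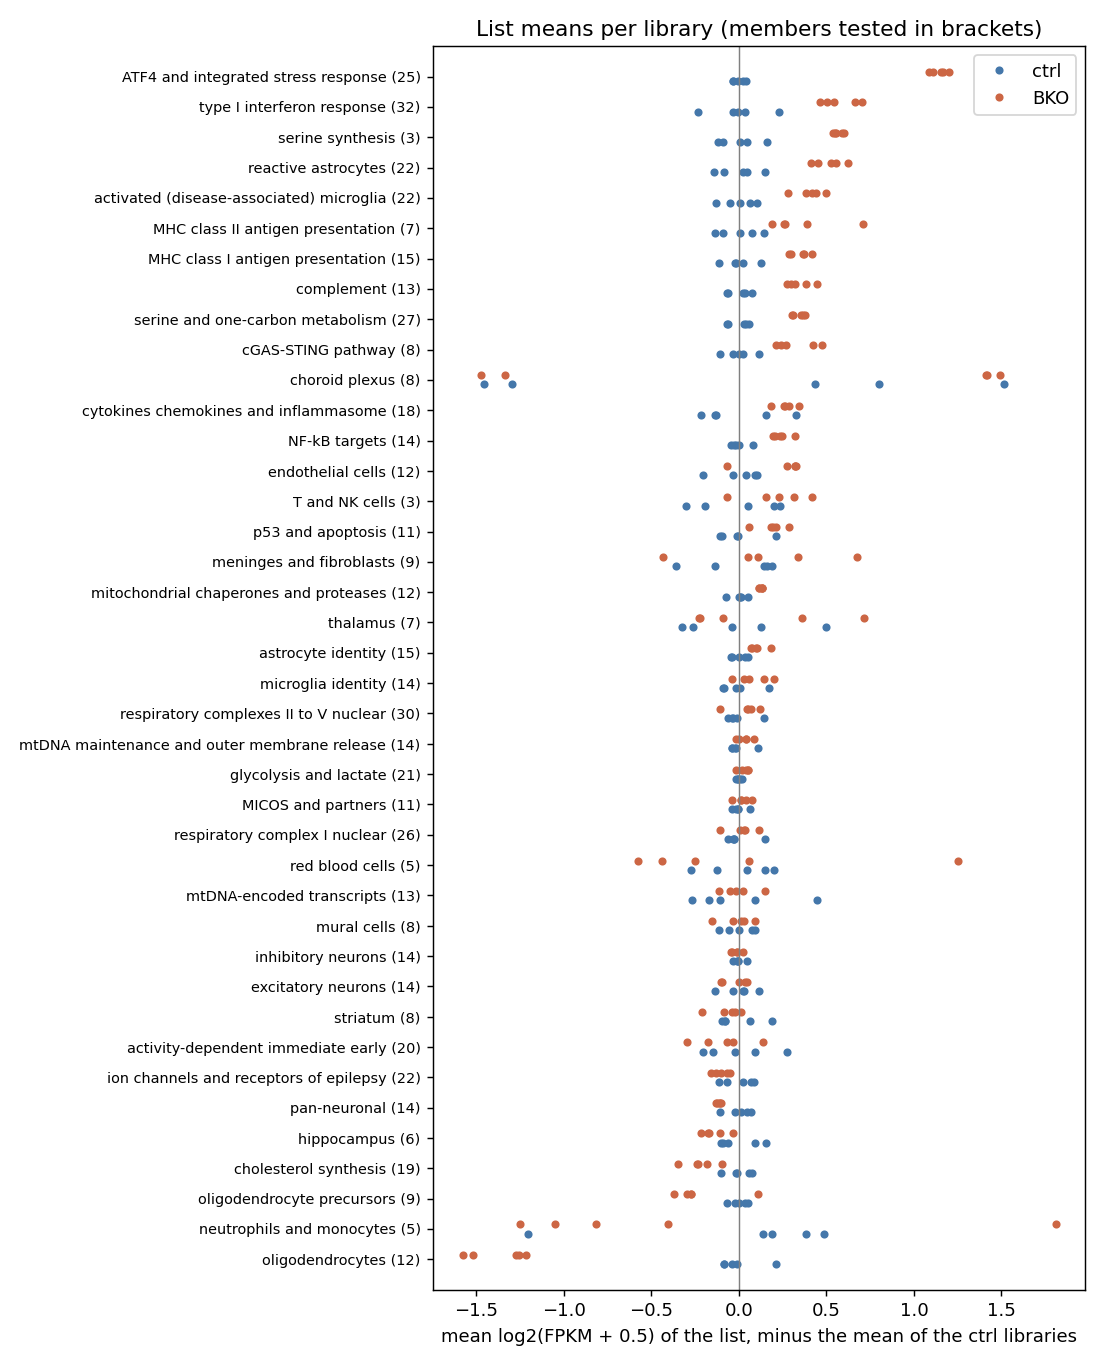
Mean log2(FPKM + 0.5) of each list with at least 3 tested members in each of the 10 libraries, minus the mean of the ctrl libraries. Among others, the stress response, interferon and reactive astrocyte lists put the BKO libraries apart from every ctrl library to the right. The oligodendrocyte list puts them apart to the left, and the choroid plexus list spreads widely within both labels.

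Of 14 pan-neuronal genes, 4 fell and none rose, and 7 fell when adjusted over the list alone. They were the neurofilament subunits Nefh, by 0.28 (SE 0.069, limma adjusted p = 0.0233), Nefm and Nefl, and Snap25, a protein of synaptic vesicle release. The list was called with the preset correlation (camera adjusted p = 6.45e-05) and not with an estimated one (adjusted p = 0.124 with an estimated correlation). Its mean overlapped between the groups (exact permutation test, 2-sided, p = 0.0238, and 0.0610 adjusted over the lists). The call on Nefh was lost without ctrl 2, ctrl 3, BKO 3 or BKO 4 (limma adjusted p = 0.0518 to 0.0703). The number that fell was 2 in the replicate block, 1 after rescaling to an equal sum or quantile normalization, 0 without ctrl 2, ctrl 3, BKO 3 or BKO 4, 1 without ctrl 1 or BKO 5, and 2 without BKO 1 or BKO 2. The calls on Nefm and Nefl were lost without ctrl 1, ctrl 2, ctrl 3, BKO 1, BKO 3, BKO 4 or BKO 5, and that on Nefl also without BKO 2 (limma adjusted p = 0.0586 to 0.119). That on Snap25 was lost without any 1 of ctrl 1 to 4 and BKO 2 to 5 (limma adjusted p = 0.0535 to 0.107). In the replicate block Nefl (limma adjusted p = 0.102) and Snap25 (limma adjusted p = 0.0584) were lost, and without the filter Nefm (limma adjusted p = 0.0511) and Snap25 (limma adjusted p = 0.139). Of 22 ion channel and receptor genes of epilepsy, 4 fell and none rose, and 7 fell when adjusted over the list alone. Scn1a, a voltage-gated sodium channel, fell by 0.28 (SE 0.0605, limma adjusted p = 0.0116), and Kcna1, a potassium channel, fell by 0.27 (SE 0.0668, limma adjusted p = 0.0294). The list was called with the preset correlation (camera adjusted p = 0.000296) and not with an estimated one (adjusted p = 0.398 with an estimated correlation). Its mean overlapped between the groups (exact permutation test, 2-sided, p = 0.0794, and 0.141 adjusted over the lists). The number that fell was 1 without ctrl 2, ctrl 3, BKO 2 or BKO 5 and 2 without BKO 3 or BKO 4. The call on Kcna1 was lost without ctrl 2, ctrl 3, BKO 1, BKO 2, BKO 4 or BKO 5 (limma adjusted p = 0.0514 to 0.0875) and in the replicate block (limma adjusted p = 0.0573). None of 14 markers of excitatory neurons changed (limma; 1 lower at unadjusted p under 0.05; camera adjusted p = 0.470), but Nrgn passed without ctrl 5 (limma adjusted p = 0.00911) and in a robust fit (limma adjusted p = 0.0405). Of 14 markers of inhibitory neurons, 1 fell, and 1 when adjusted over the list alone (camera adjusted p = 0.742). It was the potassium channel Kcnc1, by 0.20 (SE 0.0465, limma adjusted p = 0.0188), whose call was lost without ctrl 2 (limma adjusted p = 0.0509) and in the replicate block (limma adjusted p = 0.0516). No activity-dependent immediate early gene of 20 changed (limma; 1 higher and 4 lower at unadjusted p under 0.05; camera adjusted p = 0.367). Without ctrl 1, however, 2 rose and 2 fell, and without BKO 5, 1 fell. Arc, a synaptic plasticity gene, stood at 118 ± 35.0 FPKM in ctrl and 84.1 ± 20.8 FPKM in BKO (SD, n = 5 each; limma adjusted p = 0.214).

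Of 12 mitochondrial chaperones and proteases, 3 rose, and 3 when adjusted over the list alone. The chaperone Hspa9 rose by 0.42 (SE 0.0358, limma adjusted p = 2.6e-06), the protease Lonp1 by 0.30 (SE 0.0421, limma adjusted p = 0.00033) and Hspe1 by 0.19 (SE 0.049, limma adjusted p = 0.0353). The call on Hspe1 was lost without ctrl 1, ctrl 3, ctrl 4, BKO 1, BKO 3, BKO 4 or BKO 5 (limma adjusted p = 0.0658 to 0.0880), in the replicate block (limma adjusted p = 0.0719) and without the filter (limma adjusted p = 0.0520). The list was called with the preset correlation (camera adjusted p = 0.000317) and not with an estimated one (adjusted p = 0.0746 with an estimated correlation). None of the 13 transcripts of mitochondrial DNA changed (limma; 1 higher at unadjusted p under 0.05; camera adjusted p = 0.694). COX1, a subunit of cytochrome c oxidase, stood at 20769 ± 439 FPKM in ctrl and 19485 ± 771 FPKM in BKO (SD, n = 5 each). COX2, COX3, ATP6, ATP8 and ND4L were listed far lower, COX2 at 3.71 ± 2.05 and 5.09 ± 3.19 FPKM (SD, n = 5 each). Their values are too low to be read as levels of these transcripts. A near-identical copy in the nuclear genome can take their reads or leave them unassigned, which was not tested. The result on the 13 transcripts thus rests on the other members. None of 26 nuclear genes of respiratory complex I and none of 30 of complexes II to V changed (limma; none at unadjusted p under 0.05; camera adjusted p = 0.736 and 0.182). Without ctrl 5, 1 gene of complex I rose. The list of complexes II to V was called upward after rescaling to an equal sum (camera adjusted p = 0.0470) or quantile normalization (camera adjusted p = 0.000782), with library weights (camera adjusted p = 0.0288), and without ctrl 5 (camera adjusted p = 0.00173) or BKO 2 (camera adjusted p = 0.00102). None of 14 genes of mitochondrial DNA maintenance and release changed (limma; 1 higher at unadjusted p under 0.05; camera adjusted p = 0.429), but 1, Bax, passed in several fits. It rose after rescaling to an equal sum (limma adjusted p = 0.0321), in the replicate block (limma adjusted p = 0.0181), with library weights (limma adjusted p = 0.0267), and without ctrl 5 (limma adjusted p = 0.0145) or BKO 2 (limma adjusted p = 0.0302). None of 21 of glycolysis and lactate changed (limma; 3 higher at unadjusted p under 0.05; camera adjusted p = 0.484), and that list was called upward after quantile normalization (camera adjusted p = 0.0360).

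Of 11 p53 and apoptosis genes, 1 rose and 1 fell, against 3 and 1 when adjusted over the list alone. Cdkn1a, an inhibitor of the cell cycle, rose by 0.89 (SE 0.120, limma adjusted p = 0.000221) and Sesn1, a stress-induced protein, fell by 0.20 (SE 0.0525, limma adjusted p = 0.0350). The call on Sesn1 was lost without ctrl 2, ctrl 3, ctrl 5, BKO 2, BKO 4 or BKO 5 (limma adjusted p = 0.0597 to 0.0908), in the replicate block (limma adjusted p = 0.0953) and after rescaling to an equal sum (limma adjusted p = 0.0597). In these last fits, and without ctrl 5, BKO 2 or BKO 3, 2 genes rose. That list was called with the preset correlation (camera adjusted p = 0.0452) and not with an estimated one (adjusted p = 0.306 with an estimated correlation). Its call was also lost after rescaling to an equal sum (camera adjusted p = 0.0523), without a trend in camera's variances (camera adjusted p = 0.0754), without genes of other lists (camera adjusted p = 0.120) and without ctrl 1, ctrl 2, ctrl 3, ctrl 4, BKO 1 or BKO 4 (camera adjusted p = 0.0515 to 0.104). The list mean overlapped between the groups (exact permutation test, 2-sided, p = 0.0397, and 0.0904 adjusted over the lists).

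Markers of other cell types and regions that a cortical sample can hold were measured in the same way. No endothelial gene of 12 changed (limma; 4 higher at unadjusted p under 0.05), with 3 higher when adjusted over the list alone, 4 rising without BKO 1, 2 without ctrl 4 and 1 in the replicate block. The endothelial list was called upward with the preset correlation (camera adjusted p = 0.000905) and not with an estimated one (adjusted p = 0.373 with an estimated correlation). Its mean overlapped between the groups (exact permutation test, 2-sided, p = 0.0397, and 0.0904 adjusted over the lists). None of the mural (8 tested), meningeal (9), choroid plexus (8), red blood cell (5), neutrophil and monocyte (5), T and NK cell (3), B cell (2), striatal (8), hippocampal (6) or thalamic (7) genes changed (limma). At unadjusted p under 0.05 there was 1 lower mural, 1 higher meningeal, 1 higher T and NK cell, 1 lower hippocampal and 1 higher thalamic gene, and none in the other lists. Adjusted over the list alone, 1 T and NK cell gene was higher. The camera adjusted p was 0.848 for mural, 0.454 for meningeal, 0.594 for choroid plexus, 0.975 for red blood cell, 0.524 for neutrophil and monocyte and 0.975 for T and NK cell genes. It was 0.210 for striatal, 0.364 for hippocampal and 0.588 for thalamic genes, and B cells had too few members for the test. The T and NK cell list went down by its median (-0.15) and its test and up by its mean (0.21), and 1 member rose without ctrl 5 or BKO 2 and in the replicate block. Without BKO 3 the meningeal list rose (camera adjusted p = 0.0189), as did 1 member. Without BKO 2 the neutrophil and monocyte list fell (camera adjusted p = 0.00784), as did 1 member. Without BKO 5 the red blood cell list fell (camera adjusted p = 0.0157), as did 1 member. Ttr, the transthyretin of the choroid plexus, named after its values were seen, stood at 1098 to 2720 FPKM in ctrl 1, ctrl 3, ctrl 5, BKO 1, BKO 2 and BKO 5 and at 38.9 to 89.9 FPKM in the other 4 libraries.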

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

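The tests of explanations and the splits of the libraries in this part were chosen after the results were seen. In each group of 5 libraries, a library is listed when its gap to the nearest other exceeds 0.71 of the group's range. This held in 24 of 337 groups, and chance gives about 1 in 20, or 16.9.

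Among genes that rose or fell in BKO, single libraries stood apart as follows. Phgdh was 94.0 FPKM in BKO 2 against 99.3 to 101 in the other BKO libraries, a gap of 0.806 of the range. Psat1 was 100.04 FPKM in ctrl 5 against 81.0 to 83.9 (0.849). Hmox1 was 27.7 FPKM in BKO 5 against 37.0 to 40.4 (0.732). Opalin, an oligodendrocyte membrane protein, was 68.5 FPKM in ctrl 5 against 43.4 to 49.4 (0.763). H2-D1 was 35.8 FPKM in ctrl 3 against 31.7 to 32.4 (0.839). In BKO 2, B2m was 401 FPKM against 351 to 360 (0.814), Cd74 was 16.1 FPKM against 8.39 to 10 (0.791), and Vim was 49.0 FPKM against 37.1 to 39.6 (0.792). Kcnc1 was 65.5 FPKM in BKO 1 against 71.5 to 72.7 (0.836).

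Among genes that did not pass, Reln, a protein of interneurons, was 9.47 FPKM in ctrl 5 against 12.2 to 12.8 (0.821) and 15.8 FPKM in BKO 4 against 12.7 to 13.3 (0.799). Olig2, a transcription factor of the oligodendrocyte lineage, was 22.9 FPKM in BKO 2 against 13.8 to 15.4 (0.825). Ly6c1, of endothelial cells, was 27.1 FPKM in BKO 1 against 38.1 to 41.9 (0.746). Mdm2, a p53 target, was 32.9 FPKM in BKO 3 against 38.2 to 39.3 (0.826). The list means that stood apart were oligodendrocytes in ctrl 5 (higher, 0.735), oligodendrocyte precursors in BKO 2 (higher, 0.790), endothelial cells in BKO 1 (lower, 0.875), and neutrophils and monocytes in BKO 2 (higher, 0.723) and ctrl 1 (lower, 0.794). In ctrl 5 the means of mitochondrial DNA maintenance and release (0.836), respiratory complex I (0.846) and complexes II to V (0.770) stood higher.

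For the number of changed genes the count of splits cannot decide on chance. Of 100 splits of the libraries into 5 and 5, only 1, the real one, gave as many as 836. The highest of the others gave 35. Those others mix the labels, so any genotype contrast widens the spread within their groups and can lower their counts. Their counts thus do not show how many genes chance alone would call. For the 19 lists called with the preset correlation the count of splits does not exclude chance, since 14 of the 100 gave as many and the highest of the others gave 23. The other 13 of these were all among the 22 splits that moved only 1 library of each label across, and so hold much of the genotype contrast. Those 22 called a median of 19 lists, and the 77 splits that moved 2 of each called a median of 9 and at most 18. The splits were also counted with the estimated correlation, after the count with the preset correlation was seen. Of 100 splits 1, the real one, gave as many as 8 lists, and the highest of the others gave 1. Those others mix the labels, so any genotype contrast lies partly within their groups. There it can raise the correlation estimated between the genes of a list and lower the number of lists called. This count thus does not exclude chance for the number of lists either.

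Chchd3 was not lower in the libraries labelled BKO. Single wrong labels are argued against by the mean of the stress response list, where the lowest BKO library lay 1.05 above the highest ctrl library on the log2 scale, against a larger SD of 0.0455. A rise of the whole complex or a scaling shift is argued against by the 11 partner genes, whose median lay 0.167 below Chchd3 with an SD of 0.0484. An exchange of the labels of the whole groups stays open: the ratio of mean Chchd3 in ctrl to BKO was 0.889, and exon-level values, which would show whether a deletion removes reads over part of the gene, were not used here. A knockout that leaves the transcript in place, or that is confined to some cells, stays open too and was not tested.

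Oligodendrocyte transcripts were lower in the libraries labelled BKO. Scaling is argued against, since 12 of 12 members fell under each of 4 scalings. A fall of the precursor genes as large as that of oligodendrocyte genes is argued against by the precursor list, whose median was -0.12 with an SD of 0.283. By comparison, 0.5 of the fall of oligodendrocytes would be -0.71, and 8 of 9 precursor genes lay above that. A lower share of the whole lineage stays open, since the list's transcription factors of the whole lineage, Olig1 and Sox10, both fell, Sox10 to -0.89. Olig2, of the same lineage, also fell without BKO 2 (-0.26, limma adjusted p = 0.0306), the library whose mean for this list stood apart. A different piece of tissue stays open: 0 of 3 region lists differed in their means, but the share of white matter was not measured. The genotype as the labels give it stays open as a biological explanation, which these tests do not separate from the tissue taken.

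ATP6, of the mitochondrial ATP synthase, was 142 FPKM in ctrl 5 against 2.67 to 18.6 in the other ctrl libraries (0.886), or 28.1 times their median, and 26.8 FPKM in BKO 2 against 2.97 to 3.88 (0.962). More mitochondrial RNA in ctrl 5 is argued against by 6 other genes of mitochondrial DNA, whose median ratio to the other ctrl libraries was 1.01. A rise by a similar factor on every gene with a near-identical nuclear copy is argued against by COX2, COX3, ATP8 and ND4L, whose median ratio was 1.92. Their ratios were 2.07, 1.67, 2.42 and 1.77, while those of the 6 other genes were 0.876 to 1.02. A smaller rise shared by the genes with a nuclear copy thus stays open. A sequence difference in mitochondrial DNA that moves reads between the copies stays open and was not tested. No biological explanation was tested, since the library belongs to no group of its own.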

How the results depend on the processing

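Leaving out ctrl 5 and BKO 2 together was chosen after the data were seen. Camera was first run without a trend in the variances, and the trend was set after that run. The other alternatives were planned. The 836 changed genes became 702 to 905 under the planned settings with all libraries and 651 to 852 with 1 library left out, and none of them changed sign. Rescaling to an equal sum gave 856 genes, 65.3% of them higher in BKO, against 57.4% as reported, and without ctrl 5 and BKO 2 it was 61.8%. The replicate block gave 702 genes, of which 658 were shared, and it changed no list call. Of 10 libraries, 3 correlated best with the library of their own number in the other group. This neither shows nor excludes a pairing by replicate number. Without ctrl 5 and BKO 2 there were 908 genes, 667 of them shared. There the lists of complex I (camera adjusted p = 0.000428), complexes II to V (4.02e-08), striatum (0.0371) and neutrophils and monocytes (0.0289) gained a call, and NF-kB targets and MHC class II (0.0592 each) lost theirs. Of 79 named genes that passed, 12 were lost under at least 1 planned setting with all libraries, 16 with 1 library left out, and 0 reversed. Of the 19 lists, 12, 1 and 0 were.

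Chchd3 stayed higher in BKO throughout, at 0.143 to 0.196 with 1 library left out. It passed at 0.190 after rescaling to an equal sum and at 0.188 after quantile normalization. The estimated correlation left 8 lists, or 10 without a trend in the variances, the other 2 being the cGAS-STING pathway and NF-kB targets, and the activated microglia list was lost (camera adjusted p = 0.0758 and 0.112). The cause was not tested.

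Directions reversed only for genes and lists that did not pass as reported. ND4 reversed to 0.0683 after quantile normalization, as did the inhibitory neuron list (camera adjusted p = 0.919) and that of mitochondrial DNA transcripts (0.385). The T and NK cell list reversed without the filter (0.458), in the replicate block (0.904), with library weights (0.968) and without ctrl 5 and BKO 2 (0.829). The red blood cell list reversed after rescaling to an equal sum (0.844), with weights (0.974) and without ctrl 5 and BKO 2 (0.988). The choroid plexus list reversed with weights (0.974) and the cytokine list with the stricter filter (0.974). With 1 library left out some lists reversed in some fits. Over all these fits, reversed or not, camera adjusted p ran from 0.0157 to 0.969 for red blood cells, 0.598 to 0.972 for mural cells, 0.107 to 0.978 for choroid plexus, 0.887 to 0.990 for T and NK cells, 0.0577 to 0.972 for complex I, 0.210 to 0.943 for thalamus, 0.0189 to 0.956 for meninges and 0.456 to 0.959 for mitochondrial DNA transcripts. The reversed fits alone gave 0.0157 to 0.969 for red blood cells, 0.869 to 0.972 for mural cells, 0.965 to 0.969 for choroid plexus, 0.887 to 0.990 for T and NK cells, 0.716 and 0.959 for complex I, 0.792 for thalamus, 0.956 for meninges and 0.925 for mitochondrial DNA transcripts. Of the reversed fits only that of the red blood cell list without BKO 5 passed, downward. The cause of these reversals was not tested. DESeq2 and edgeR were not run, since no counts were used here. What depth limits is unknown for the same reason.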

Other observations

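The 4 lists in this part were chosen after the data were seen, and so were their tests, which describe these libraries only. Of 20 cytosolic tRNA synthetases, which ATF4 induces in part, 6 rose and none fell, and Eprs1 rose by 0.61 (SE 0.0435, limma adjusted p = 4.46e-07). Of 19 NRF2 targets, 7 rose and 1 fell. The antioxidant transporter gene Slc7a11, which also belongs to the stress response list, rose by 1.85 (SE 0.0841). The detoxifying hydrolase Ephx1 rose by 0.87 (SE 0.056), while Gstm1 fell by 0.26 (SE 0.0671, limma adjusted p = 0.0340). Of 12 interferon-induced GTPases, 6 rose and none fell, among them Gbp3 by 1.15 (SE 0.116), Gbp6 by 1.26 (SE 0.175) and Irgm1 by 0.46 (SE 0.0726). Of 14 enzymes of myelin lipids, 7 fell and 1 rose: the desaturase Scd1 fell by 1.27 (SE 0.0711, limma adjusted p = 3.76e-08), and Acsbg1 rose by 0.29 (SE 0.0537). The camera adjusted p over these 4 lists was 2.38e-07, 2.38e-07, 1.67e-08 and 4.77e-08 in that order, and 0.00989, 0.00989, 0.00124 and 0.00989 with an estimated correlation. Each list mean had the smallest exact permutation p of 0.00794.

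Ttr differed 70.0 times between the highest and the lowest library, and high and low libraries occurred under both labels. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in all 10 libraries. The share of the FPKM sum from mitochondrial DNA was 7.05% to 8.16%. COX2, COX3, ATP6, ATP8 and ND4L, which were listed far lower than COX1, added little to it. Correlations between libraries across genes were 0.984 to 0.993, and no pair was a duplicate.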
